A study of Rattus norvegicus with 10 samples.

How the data were processed

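Gene expression was measured on 10 Agilent arrays with 2 colours in adult rat cardiomyocytes. RNA was extracted with an SV total RNA kit from Promega and labelled with an Agilent kit for linear amplification of small RNA amounts, per the labels' protocols. The authors deposited a table of 1 value per probe and array, read here as log2 ratios of both channels. The base of the logarithm, the centring, the direction of the ratio and the normalisation were not given in the sources used here. Values ran from -7.15 to 6.94, further than a log10 ratio of a standard scanner allows, and a natural log was not excluded. Values are therefore printed as deposited log ratios and not as fold changes. The array medians lay between -0.0101 and 0.0082, close to a centred scale. No scanner data were used here, so background, signal and control spots could not be checked. Columns of the table not used numbered 0.

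Arrays were grouped by the form of fractalkine and by the dye of the treated RNA as the labels give them. limma version 3.58.1 in R version 4.3.3 fitted all 10 arrays together, with an effect for each form that changed sign with the dye orientation and a common dye term. Contrasts tested the full-length protein, the chemokine domain, their average and their difference with moderated statistics. The adjusted p is that of Benjamini and Hochberg over all 44290 probes, with a threshold of 0.05. This fit reads the values as Cy5 over Cy3. The reading as treated over control was fitted as an alternative, with the sign of the dye term following the orientation. The design, both readings, the gene lists, the first set of other settings and the rule for named genes were fixed before the data were examined. The labels call the arrays of a form separate but do not say which came from the same isolation, and the series description counts fewer samples than arrays, so p-values measure the spread between arrays, part of which may be technical. The turned values given with SDs had the fitted dye term removed and the sign changed on arrays with treated RNA in Cy3.

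The platform annotation covered 23583 of the 44290 probes, 23535 with 1 gene symbol and 48 with several, and 20707 had none. It was checked against the values by comparing probes of the same symbol and of the same accession. Over 3207 accessions the mean profile correlation of probe pairs was -0.008. In 24 accessions with at least 8 probes the intraclass correlation over arrays lay between -0.030 and 0.026. The planned feature was the gene symbol, with probes averaged. As the symbols were not borne out, the probe became the feature, and the average per symbol was kept as an alternative. The rule for named genes allowed, without gene names, at most 2 probes on either side, taken as those with the largest log ratios among probes past the threshold with the same turned sign on all arrays. Genes that the rule would always name, such as natriuretic peptides, myosin heavy chains and the fractalkine receptor, are not reported for the same reason.

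The 21 gene lists held sarcomere, calcium handling and ion channel, hypertrophy, fatty acid, glycolysis, oxidative phosphorylation, oxidative stress, unfolded protein and heat shock, apoptosis, cell cycle, ribosomal protein, matrix, NF-kB, interferon, MAP kinase and fractalkine genes and markers of fibroblasts, endothelium, smooth muscle, leukocytes and blood cells. They were tested on symbol averages with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Of 100 draws of random lists, 3 had a call.

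The fit was tested on simulated data of 44290 probes with 200 changed and the spread of the real arrays. Values were drawn independently for each probe and array, whereas real arrays with the same orientation correlated at -0.37 to 0.25. Recovery and counts with no effect may therefore differ in the real data. With both forms changed alike, the average recovered 41.8% of changes of 0.25 log units, 100% of 0.5 and 100% of 1, with 9 false calls. The full-length contrast recovered 14.9%, 92.5% and 100%, and the domain contrast 5.97%, 94% and 100%, with 1 and 21 false calls. With the full-length protein alone changed, the difference recovered 1.49%, 56.7% and 100% of the same sizes, with 4 false calls. With no effect, least squares called 0 probes in each contrast, and array weights called 1 for the average. Robust regression called 0, 40, 2 and 5 for the full-length protein, the domain, the average and the difference. Its unadjusted p was under 0.05 for 4132, 6250, 5089 and 5367 probes in the same order. Least squares gave 1359, 2771, 1912 and 2204, so the p-values of robust regression ran low.

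The other settings fixed in advance were the other reading, no dye term, a dye term per form, centring, scaling, array weights, robust empirical Bayes, a filter on probes of small spread, the array number as a block, each array left out in turn, and the other list tests. Added after the data were seen were the values of full-length array 5 turned (which turns its dye effect too). Its dye label exchanged in the model, with the values as deposited, was added then as well. So were full-length arrays 4 and 5 left out, removal of a trend over the file order and robust regression. Averages per symbol were the planned feature and became an alternative when the probe replaced them. The trend was a local mean over a window of 15 by 15 positions of the table folded into rows.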

Results

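Fractalkine (CX3CL1) is a chemokine whose chemokine domain sits on a mucin-like stalk, and the protein occurs both anchored in the membrane and shed from it. Gene expression was measured in cardiomyocytes isolated from adult rat hearts after 24 hours with full-length fractalkine or with its chemokine domain alone, residues 25 to 100. Control cells received bovine serum albumin. Each of 10 arrays compared treated and control cells of the same isolation in the dyes Cy3 and Cy5, with 5 arrays per form of the protein. Treated RNA carried Cy5 on arrays 1 and 2 and Cy3 on arrays 3 to 5 of each form. Any other difference between these sets of arrays therefore cannot be separated from the dye orientation. The cells came from 3 isolations, and the isolation of each array was not given in the sources used here. The series description counts 5 treated and 5 control samples for these 10 arrays, so arrays may share RNA, and n counts arrays throughout. Each array held 44290 log ratios with 0 missing, and the medians of the arrays lay between -0.0101 and 0.0082. The standard deviation over probes ranged from 0.146 to 0.31 between arrays. The number of arrays limited the precision, and no signal intensities were used here.

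Over both forms together, the values weakly followed the dye that carried the treated RNA. Over all probes, 18 of the 21 pairs of arrays with the same dye orientation correlated above 0, with a median Pearson r of 0.06. Of the 24 pairs with opposite orientation, 19 correlated below 0, with a median of -0.08. Among the arrays of the chemokine domain, 4 of 4 pairs with the same orientation lay above 0 and 5 of 6 pairs with opposite orientation lay below 0. Among the full-length arrays, 2 of 4 pairs with the same orientation lay above 0 and 5 of 6 with opposite orientation lay below 0. Full-length arrays 4 and 5, which had the same orientation, correlated at -0.37, so their direction relative to each other was not settled. These correlations are across probes, which are not independent replicates.

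**Figure D1:**
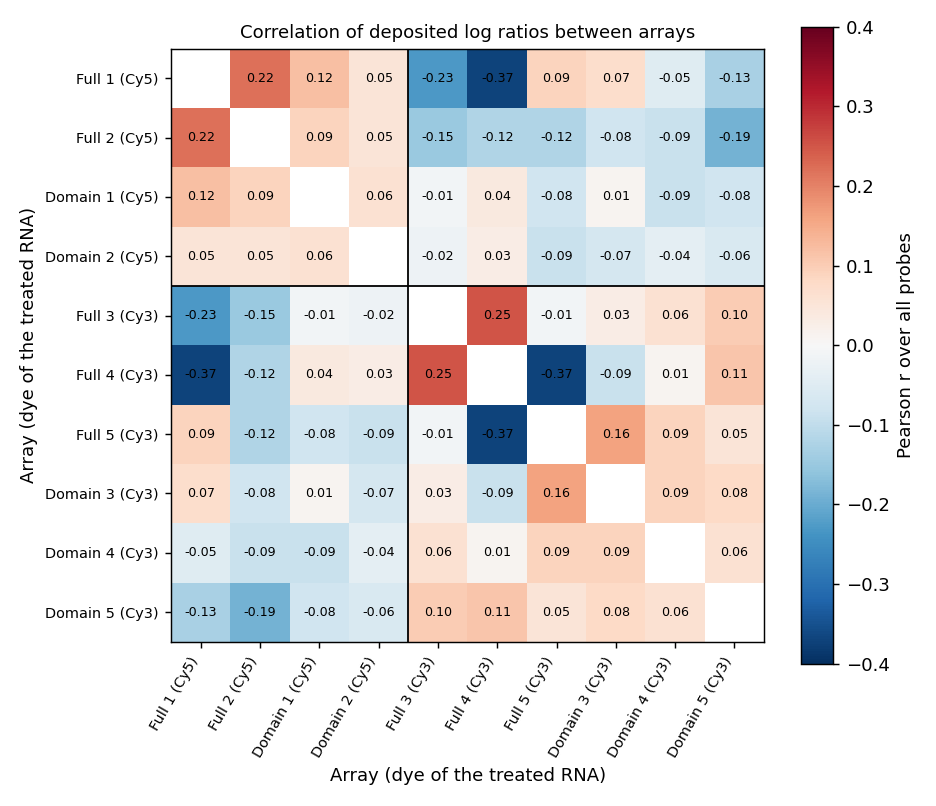
Pearson r of the deposited log ratios over 44290 probes for each pair of the 10 arrays, with the dye of the treated RNA in parentheses and black lines between the orientations. Pairs with the same orientation had a median of 0.06 and pairs with opposite orientation a median of -0.08, while full-length arrays 4 and 5 lay at -0.37.

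The signs of the 10 values of a probe were counted too. With mirror images counted as one, 10 arrays allow 512 sign patterns. The pattern that switched sign with the dye orientation held 501 probes, more than each of the other patterns, of which the highest held 337 and the median of all patterns was 73. The pattern with the same sign on all 10 arrays held 61 probes and ranked 387. Within a form, with 16 patterns of 5 arrays, the orientation held 4349 probes and ranked first for the domain. For the full-length protein it held 4615 and ranked behind the pattern with array 5 turned, which held 5081. Values given as Cy5 over Cy3 switch sign with the orientation where treated and control cells differ and keep their sign under a dye effect. Values already turned to treated over control do the reverse. The direction of the deposited values was not given in the sources used here, so each comparison is reported under both readings, and no direction of change in treated cells is given.

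**Figure D2:**
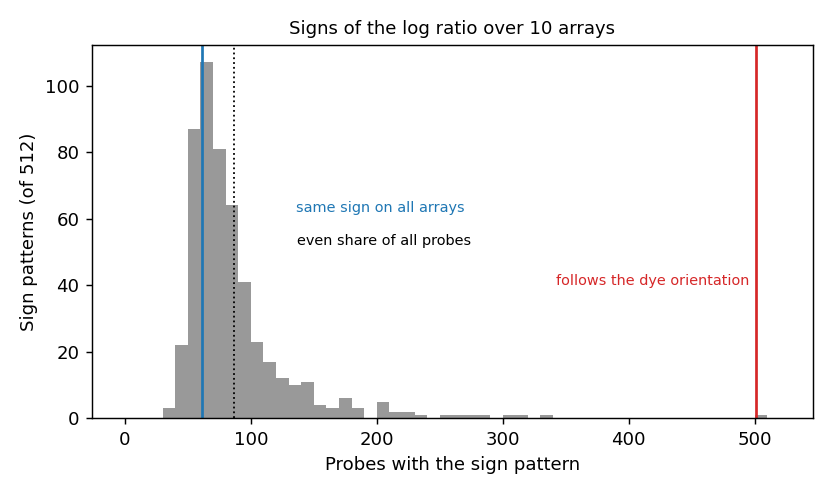
Histogram of the number of probes (horizontal axis) in each of the 512 sign patterns of the log ratio over 10 arrays (vertical axis, patterns). The red line marks the pattern that follows the dye orientation at 501 probes, the blue line the pattern with the same sign on all arrays at 61, and the dotted line an even share of 86.5.

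The first comparison asked which transcripts differ between cells treated with full-length fractalkine and control cells. Read as Cy5 over Cy3, 0 of 44290 probes passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.159. The unadjusted p was under 0.05 for 3438 probes, or 7.76%, against 1359 probes in simulated data with no effect. Simulated probes and arrays were independent, unlike the real ones, so this excess does not measure a treatment effect. Read as treated over control, 0 probes passed and 625 had an unadjusted p under 0.05. The median 95% interval of a probe reached 0.159 log units to either side, against a median size of the log ratio of 0.0569. Read as Cy5 over Cy3, 131 probes lay beyond 0.5 in size and 1 beyond 1. Of these 0 passed, so changes of that size were not excluded. The count depended on array 5: it was 0 without array 4, 351 without array 5, 148 with the values of array 5 turned, 529 with its dye label exchanged and 1 without both arrays. It was 484 with array weights and 37 with arrays scaled to the same spread. It was 753 with robust regression, whose unadjusted p was under 0.05 for 4132 probes in simulated data with no effect.

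The same question was asked of the chemokine domain. Read as Cy5 over Cy3, 1 of 44290 probes passed, probe 31281, with a log ratio of 0.78 (95% interval 0.61 to 0.94, adjusted p = 0.0023 in limma). Its sign followed the orientation on 5 of 5 arrays, and its turned values averaged 0.78 ± 0.09 (SD, n = 5). The unadjusted p was under 0.05 for 4152 probes, or 9.37%, against 2771 in the same simulation of independent probes and arrays with no effect. The counts with no effect differed between the forms, so these shares do not rank the forms. Read as treated over control, 0 probes passed in limma and 2367 had an unadjusted p under 0.05. The median interval reached 0.159 to either side. In simulated data this contrast gave 21 false calls with both forms changed alike and 0 with no effect. Read as Cy5 over Cy3, 27 probes lay beyond 0.5 in size and 9 beyond 1. Only probe 31281 passed, so changes of that size were not excluded. The count was 0 without domain array 1 or 2, 0 with the values of full-length array 5 turned or its dye label exchanged, 4 without full-length array 4 and 7 without full-length arrays 4 and 5. In the settings just named that ended the call, probe 31281 still had log ratios of 0.79, 0.74, 0.80 and 0.76 in the same order. The count was also 0 with probes averaged per symbol, the planned feature. It was 1150 with robust regression, a fit that called 40 probes in this comparison in simulated data with no effect.

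Averaged over both forms, 41 probes passed in limma when the values were read as Cy5 over Cy3. Their log ratios ran from 0.253 to 0.637 for 32 probes and from -0.262 to -0.403 for 9. Turned values of 39 of the 41 had the same sign on all 10 arrays, which is no separate support, since the average chose the probes. The unadjusted p was under 0.05 for 4747 probes, or 10.7%, against 1912 in the simulation with no effect. Its probes and arrays were independent, so this excess too does not measure a treatment effect. Among the probes that passed with the same turned sign on all 10 arrays, probe 31281 had the highest average, 0.64 (95% interval 0.52 to 0.75, adjusted p = 0.00039), with turned values of 0.64 ± 0.21 (SD, n = 10). Probe 23161 followed at 0.56 (0.35 to 0.76, adjusted p = 0.048), with turned values that varied by 0.35 (SD, n = 10). On the other side lay probe 15920 at -0.40 (-0.54 to -0.26, adjusted p = 0.035) and probe 20480 at -0.34 (-0.45 to -0.23, adjusted p = 0.026), with standard deviations of 0.24 and 0.14 (n = 10). The dye term of this fit passed for 0 probes in limma, with an unadjusted p under 0.05 for 1403.

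Read as treated over control, the average passed for 0 probes in limma, and 1353 had an unadjusted p under 0.05. The averages of the 4 probes were then -0.01, -0.07, -0.04 and -0.04 in the same order. In that reading the component that followed the orientation was the dye term, which passed for 23 probes and had an unadjusted p under 0.05 for 4415. Read as Cy5 over Cy3, the average count was 4 with a dye term per form, which kept 3 of the 41 probes. It was 124 without a dye term, 153 with scaled arrays and 249 with array weights. It was 2081 with robust regression, whose unadjusted p was under 0.05 for 5089 probes in simulated data with no effect. With probes averaged per symbol, the planned feature, it was 28. It was 171 without full-length array 5, 67 without full-length array 4, 77 without both and 0 with the values of array 5 turned or its dye label exchanged. It lay between 1 and 3 without any 1 of the other arrays, full-length 1, 2 and 3 and domain 1 to 5. Probe 31281 stayed past the threshold without any 1 array (adjusted p 0.00021 to 0.0084 in limma) and lost it with the values of full-length array 5 turned (log ratio 0.51, adjusted p = 0.12) or its dye label exchanged (0.49, adjusted p = 0.096). With a dye term per form, probes 23161, 15920 and 20480 no longer passed (adjusted p 0.086, 0.062 and 0.051), with the same log ratios of 0.56, -0.40 and -0.34. Without any 1 of these 8 arrays probes 23161 and 15920 no longer passed (0.081 to 0.22 and 0.064 to 0.21), and probe 20480 no longer passed without 7 of them, domain array 1 excepted (0.064 to 0.18). With 1 array left out, their log ratios ranged from 0.48 to 0.65, from -0.44 to -0.36 and from -0.40 to -0.31.

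**Figure D3:**
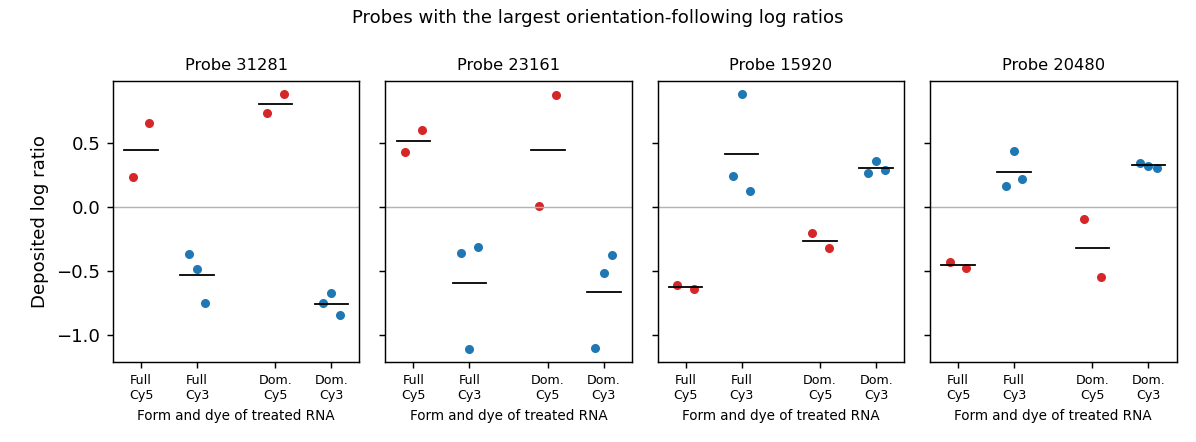
Deposited log ratios (vertical axis) of probes 31281, 23161, 15920 and 20480 by form and dye of the treated RNA (horizontal axis), with a point per array (2 with treated RNA in Cy5 and 3 in Cy3 per form) and bars at the means. Probe 31281 had positive values on the 4 arrays with treated RNA in Cy5 and negative values on the others.

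The remaining comparison asked whether the full-length protein and its chemokine domain differ in their response. In limma 0 of 44290 probes passed, with a smallest adjusted p of 0.861 and 2375 probes, or 5.36%, at an unadjusted p under 0.05. Simulated data with no effect and independent probes and arrays gave 2204 such probes. Read as treated over control, 0 passed and 1287 had an unadjusted p under 0.05. Probe 31281 had a log ratio of 0.50 with the full-length protein (SD 0.21, n = 5), which differed from that with the domain by -0.28 (95% interval -0.51 to -0.05, adjusted p = 0.86 in limma). The difference was -0.01 (-0.42 to 0.39) for probe 23161, -0.21 (-0.49 to 0.06) for probe 15920 and -0.02 (-0.24 to 0.19) for probe 20480. Read as treated over control, the differences of these probes were -0.01 for probe 31281, 0.07 for 23161, -0.08 for 15920 and -0.08 for 20480. The median interval of a probe reached 0.223 to either side. In simulated data with the full-length protein alone changed, this test recovered 1.49% of differences of 0.25 log units, 56.7% of 0.5 and 100% of 1. In the deposited values 151 probes had a difference beyond 0.5 in size and 13 beyond 1, and 0 of them passed, so differences of that size were not excluded.

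Across probes, the log ratios of both forms correlated at a Pearson r of 0.186 and a Spearman rho of 0.170, with a covariance of 1.97e-03. Simulated unchanged arrays with separate control RNA gave a Pearson r of 0.00785 and a covariance of 5.37e-05. Those arrays were drawn independently, so their r lay near 0 by design and does not test chance alignment of correlated arrays. Simulated arrays with control RNA shared by array number gave 0.484 and 3.31e-03, but there arrays with the same number correlated at 0.49 to 0.51, against 0.01 to 0.12 in the deposited values. Whether arrays of both forms shared control RNA, as the 5 control samples of the description allow, was not given in the sources used here. Part of the excess over separate controls may therefore come from shared controls. Part may also come from a difference between lower and higher numbered arrays, which the orientation follows in both forms. The component that did not follow the orientation correlated at 0.0524. The Pearson r was 0.074 without full-length array 5, 0.26 without full-length array 4, 0.020 with the values of array 5 turned and -0.012 with its dye label exchanged.

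The gene annotation of the probes was not borne out by the values. Pairs of probes annotated with the same gene symbol, over 5658 symbols, correlated between -0.022 and 0.007 (Spearman) on the 10 arrays. The mean correlation of their profiles over the arrays was -0.007, against 0.001 for random pairs. Probes are therefore reported by number, and no gene is named. Of 21 gene lists for cardiomyocyte functions, inflammatory signalling and other cell types, with 388 of 419 genes matched by symbol, 0 passed in the camera test of limma in each of the 4 contrasts, with smallest adjusted p of 0.396 for the full-length protein, 0.40 for the domain, 0.485 for the average and 0.493 for the difference. Members passing over all features numbered 0, and adjusted over the list alone they numbered 3, 1, 9 and 1 in the same order. With an estimated correlation the smallest adjusted p was 0.799, 0.628, 0.780 and 0.828. Because the symbols were not borne out, these counts say nothing about the pathways.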

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

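The tests of the opposite full-length arrays were chosen only after the result was seen. In the groups of 5 arrays, 18 sets of values were searched for an array far from the others, and 1 was found. Chance gives about 1 in 20 such groups. Full-length array 4 held 66 probes with a log ratio beyond 2 in size, against 1 to 11 on the other full-length arrays. Of these 66, 8 stayed under 0.5 on each of the other arrays.

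Full-length arrays 4 and 5 had the same dye orientation and correlated at -0.37. A wrong dye label on array 5 stays open, as the counts go both ways. Over all arrays, turning it lowered the probes that followed the orientation from 501 to 313, the smallest fall for any of the 10 arrays. Turning array 4 lowered them to 306, so this count hardly separates both arrays. With domain arrays 1 to 5, array 5 correlated at -0.08, -0.09, 0.16, 0.09 and 0.05, with the signs that its label gives. Array 4 correlated at 0.04, 0.03, -0.09, 0.01 and 0.11, in part against its label. Within the full-length arrays, turning array 5 raised the probes that followed the orientation from 4615 to 5081, and turning array 4 lowered them to 3304. Exchanging the dye label of array 5 raised the calls for that form from 0 to 529. Extreme spots and the largest group of probes with similar profiles are argued against as the whole cause. Among probes within 1 log unit on both arrays r stayed at -0.28, and without the probes that followed that group at -0.26. A difference between isolations stays open, as the isolation of each array was not used here, and no biological explanation was tested.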

How the results depend on the processing

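The alternatives that turned the values of full-length array 5 or exchanged its dye label were chosen only after the result was seen. So were those that left out full-length arrays 4 and 5, removed a position trend or used robust regression. The average per symbol was the planned feature, and the probe replaced it after the annotation was checked against the values. Counts are of probes passing in limma for the full-length protein, the domain, the average and the difference, with 0, 1, 41 and 0 as reported. The cause of each change was not tested, except that leaving arrays out lowers the number of arrays. Read as treated over control, the domain and the average gave 0 and 0 and the correlation of the forms 0.046. Without a dye term the domain gave 2 and the average 124. A dye term per form gave 1, 4 and 1 for the full-length protein, the average and the difference, and the 4 held 3 of the 41 probes. Robust empirical Bayes ended the call of probe 23161 for the average (adjusted p = 0.072), and turning the values of array 5 ended those of the 4 named probes (0.12 to 0.13), with log ratios of 0.51, 0.50, -0.38 and -0.31 against 0.64, 0.56, -0.40 and -0.34. Exchanging its dye label ended them too (0.096 to 0.12), with 0.49, 0.51, -0.37 and -0.29. Scaling gave 37 for the full-length protein and 153 for the average, and array weights 484 and 249. Robust empirical Bayes gave 66 for the average. Without the lowest quartile of probes by spread the counts were 36 and 66 for the full-length protein and the average. With the values of array 5 turned the counts were 148, 0 and 0 for the full-length protein, the domain and the average, with a correlation of 0.020. With its dye label exchanged they were 529, 0 and 0, with a correlation of -0.012. Without full-length arrays 4 and 5 they were 1, 7 and 77, and 28 of the 41 probes were among the 77. Robust regression, whose p-values ran low in simulated data with no effect, gave 753, 1150, 2081 and 1. Averages per symbol, the planned feature, gave 0, 0, 28 and 0, so the domain's call of 1 probe was absent there. The average gave 46 after centring and 61 after removal of the position trend, and these held the 41 probes. The count of gene lists passing stayed at 0 in the alternatives run.

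Leaving out 1 array at a time gave 0 to 351 for the full-length protein (351 without full-length array 5), 0 to 4 for the domain (4 without full-length array 4), 1 to 171 for the average (171 without full-length array 5, 67 without full-length array 4) and 0 for the difference. The correlation of the forms ranged from 0.074 to 0.26. The average held 41 of the 41 probes without full-length array 4 or 5.

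Deviations of arrays with the same number from the fit correlated at -0.08, -0.33, -0.06, -0.06 and -0.16. The fit pulls such deviations of unrelated arrays below 0, so these values do not test whether the array numbers pair the arrays. With the array number as a random block, the estimated correlation of arrays with the same number was -0.018, so no pairing by number was seen. The counts were then 0, 1, 55 and 0, and the 55 held the 41 probes. With a fixed block the difference gave 0. The random block and robust regression were not run for the gene lists, and the filter on missing values was not run because 0 values were missing.

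Read as treated over control, probe 31281 had log ratios of -0.01 for the full-length protein, 0.00 for the domain and -0.01 for the average, and probe 23161 had -0.04, -0.11 and -0.07, with a difference of 0.07. The difference for probe 23161, reported as -0.01, was 0.00 with a dye term per form, 0.11 with scaling and 0.02 with array weights, and ranged from -0.16 to 0.11 with 1 array left out. That for probe 20480, reported as -0.02, was 0.07 with the values of array 5 turned, 0.06 with its dye label exchanged and 0.07 with robust regression, and ranged from -0.07 to 0.06 with 1 array left out.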

Other observations

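The tests of the sign patterns and of the annotation were chosen only after the result was seen, and the splits of the arrays were planned. For the average, 1 of 100 assignments of dye orientations, the real one with 41 probes, gave as many. The highest other gave 2, which argues against chance. Chance is not excluded, as the assignments take arrays as independent though they may share RNA. The labels are taken as given too: with the dye label of full-length array 5 exchanged the average count was 0. For the difference the real count was 0, so that 60 of 60 splits had to give as many, and the splits say nothing about chance. The highest other gave 1. The splits of 5 arrays, 10 per form, are too few for a share under 0.05. For the domain 1 of 10 gave as many as the real 1, with a highest other of 0. For the full-length protein the real count was 0, which 10 of 10 splits had to reach, and the highest other gave 529. That split set arrays 3 and 4 against arrays 1, 2 and 5, which is the labelled orientation with the dye label of array 5 exchanged, and it points to a structure of these arrays.

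The signs of 501 probes followed the dye orientation. Chance agreement is argued against by the rank of this pattern, the first of 512. It is not excluded, as the rank takes arrays as independent though they may share RNA. Among the full-length arrays alone the orientation ranked 2 of 16. The part of a position trend that was removed does not account for the pattern of 501 probes by itself. After the removal 494 probes followed the pattern, 365 of them among the 501. Trend correlations on full-length arrays 2 and 3 fell from 0.221 and 0.249 to 0.092 and 0.108, so part of the trend stayed and was not tested. Positions were those of the table folded into rows, not known positions on the slide. Centring gave 505 but tests no shift of whole arrays, since the array medians were at most 0.0101 in size. The direction of the values was not given in the sources used here. A shared response to fractalkine and a dye effect in values already turned therefore cannot be told apart. The orientation also divided the arrays of both forms by array number. A difference between lower and higher numbered arrays, such as in isolation, would follow it too and was not tested. The correlation of the forms was 0.186, against 0.00785 in simulated unchanged arrays with separate control RNA. This correlation could arise from any of these, and shared control RNA may add to it. Chance alignment of correlated arrays was not simulated and stays open. The 61 probes with the same sign on all 10 arrays, below the median pattern of 73, exclude none of them.

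Probes annotated with the same gene shared no values. The 286 probes with a median size above 0.3 were grouped by links between profiles correlated above 0.93. The largest group held 122 probes, linked in chains, so not each pair need correlate that highly. Its median profile reached 1.58 on full-length array 4 and -0.56 to 0.43 elsewhere. This group therefore does not test whether values of a probe are reproducible over arrays, and values made up mostly of noise stay open. Its 55 annotated probes carried 55 different symbols, which is consistent with an annotation paired with another numbering of the probes, a hypothesis found in these data, but different genes moving together on that array would give it too. No biological explanation was tested.

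Positions of the table that adjoin when it is folded into rows correlated at 0.221 and 0.249 on full-length arrays 2 and 3, against 0.018 to 0.05 on the others. On domain array 5, 11 of 14 probes beyond 2 log units stayed under 0.5 on each of the other arrays.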
